A study of Escherichia coli K-12 with 12 samples.

How the data were processed

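RNA from cultures of Escherichia coli K-12 strain MG1655 was measured on Panorama gene arrays, nylon membranes that carry a spotted PCR product for each annotated open reading frame. Per the labels and the series text, RNA was copied into 33P-labelled cDNA, hybridised to the membranes and read with a phosphorimager, and the pixels of each spot were summed with ImageQuant version 3.0. The table used here holds 4290 gene spots and 24 further rows named for grid positions, in 12 columns. Its values are linear spot intensities as deposited by the authors, called normalised in the series text. How they were normalised is not given in the sources used here. The series text also says that weak spots were raised to a background mean, but no column holds a repeated lowest value of that kind (at most 2 spots share a column's lowest value), so that step is not visible in the deposited intensities. A gene, mprA, is listed at 0 in 4 columns, all of them column b of replicates 1 and 2.

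The labels give 3 biological replicates each of untreated (control) and IAA-treated cultures, with 2 columns, a and b, per culture. The series text calls a and b duplicate spots of a gene, so they were averaged as intensities and n = 3 cultures per group. The medians of the 12 columns lay between 603 and 810 and differed by up to 0.425 on the log2 scale, more than the limit of 0.25 set before the data were examined, so the columns were quantile normalized before averaging and taking log2. Values at 0 were set to the lowest positive value of their column. The 24 grid rows were left out of normalization and tests. For an array the number of membranes limits the precision, and no count of molecules stands behind a value.

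Of the 4290 gene spots, 4095 have 1 gene symbol in the platform annotation, 0 have several and 195 have none; unnamed spots were tested and are given by their spot number. Symbols were updated through the gene identifiers of the RefSeq table of assembly ASM584v2, which matched 4094 spots. The files name no genome build, so that table was used only for names, locus tags and which genes neighbour each other, and no coordinates are given.

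IAA-treated and control cultures were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 groups, no block), with Benjamini-Hochberg adjustment over 4290 spots and a threshold of 0.05. A set of 36 gene lists, written before the data were examined, was tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives; 6 of the listed genes had no spot of their name. Camera compares a list with all other genes, while fry's main p tests whether a list's genes move one way on balance, and its mixed p whether they change in either direction. Genes named in the text follow a rule fixed before the data were examined: among genes past the threshold whose groups do not overlap, the 12 largest rises and falls; if fewer than 10 passed, also the 8 per direction with the smallest unadjusted p; and from each list up to 4 members with the smallest unadjusted p. The text gives part of this set, and says where a gene was chosen after its values were seen.

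Same-numbered control and IAA cultures share a number in the labels, and the series text describes cultures that were split before treatment. Their deviations from the group means correlated at 0.12, 0.25 and 0.32 for replicates 1, 2 and 3, all above 0.1. The highest correlation with a culture of another number was 0.13, 0.028 and -0.15 in turn, so that of replicate 1 lies above its own 0.12 and its pairing is the least clear. By the limit of 0.1 the numbers were taken to pair the samples. The fit without a block, set before the data were examined, stays the main one. A fit with the replicate number as a block is given where it changes a call or a count. In that fit 21 genes were higher and 13 lower, against 3 and 0 without the block. A second structure showed in the values: each column of replicates 1 and 2 held between 755 and 933 distinct values and each column of replicate 3 between 4075 and 4097, so these sets differ in how finely their values were resolved. Both sets hold both groups, and they were used as a batch. Control 3 and IAA 3 alone make up the finer set. Their correlation of 0.32 could come from that, and cannot be told apart from pairing.

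The log2 change was found to repeat with the spot number, with a period of 96, so a position adjustment was added after seeing the data. For each culture it subtracts the median deviation of the spots at the same or an adjacent place of the repeat in up to 6 blocks of 96 on either side, leaving out the gene's own block. A second form, by place over all blocks, uses the same place only and every other block, and was also chosen after seeing the data. How spot numbers map to the membrane is not given in the sources used here. Other alternatives were the values as deposited, median centring, other ways of averaging the duplicates, a filter on dim genes, a floor at the 10th percentile, another variance model, other thresholds, 2 readings of the selection rule in the series text, and leaving out each culture in turn.

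The fits were tested on simulated data for this comparison, with 4290 genes of the measured means and spread, 200 of them changed. The fit without position adjustment recovered 91.6% of genes changed by 1 on the log2 scale and 100% of those changed by 2, averaged over 20 runs. It made 203 calls per run, against 3 in the measured data, where the adjusted threshold is therefore stricter. So these rates are not those of the measured fit. With the measured place effect added to the simulated treated cultures, the fit without position adjustment made 322 false calls per run, and the position-adjusted fit made 14. The latter recovered 90% of the changes of size 1 and 100% of those of size 2. Of the 36 lists, camera called 0 per run on unchanged simulated genes, 4.25 with the place effect and 0.05 after the position adjustment. The simulated genes were drawn independently, and every treated culture got the same place profile, the kind of shift that the adjustment removes. In the measured data adjacent spots of distant genes still correlated at 0.213 after the adjustment. So these runs do not give the false calls of either fit on the measured data.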

Results

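Transcript levels were compared between cultures of E. coli K-12 MG1655, the standard laboratory wild type, with and without IAA. The labels give only this abbreviation, which usually stands for the plant hormone indole-3-acetic acid. Cells grew with aeration at 37 °C on 0.4% L-arabinose in M9 minimal medium. The medium of all cultures also held 40 mg/l casein hydrolysate, 20 mg/l uracil and 1 mg/l thiamine. IAA was added to 0.5 mM at an OD600 of 0.6, and both kinds of culture were harvested 2 h later at an OD600 of 1.2. There were 3 control and 3 IAA cultures, each measured on a whole-genome membrane array with duplicate spots. The duplicate spots of a culture correlated across genes at r between 0.933 and 0.972 after normalization. In the values as deposited the SD of their log2 difference lay between 0.255 and 0.391. Between cultures of a group the median SD of a gene after normalization was 0.202 in controls and 0.234 with IAA on the log2 scale. The former is the spread of a difference of single spots, the latter that of duplicate means, so their sizes cannot be compared directly. IAA replicate 2 stood apart: its correlations with the other 5 cultures across genes lay between 0.799 and 0.894, and those among the other 5 between 0.873 and 0.959. Without it 2 genes, leuD and sdhB, were past the threshold used below.

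Which transcripts changed in IAA-treated cells was asked first gene by gene. leuD (b0071), the small subunit of isopropylmalate isomerase in leucine biosynthesis, was 3.65-fold higher with IAA, from 9.01 ± 0.25 to 10.88 ± 0.34 on the log2 scale (SD, n = 3 cultures each; limma log2 change 1.87, SE 0.219, adjusted p = 0.00909). aceA (b4015), isocitrate lyase of the glyoxylate shunt, was 3.03-fold higher, from 8.62 ± 0.31 to 10.23 ± 0.37 (SD, n = 3; limma log2 change 1.60, SE 0.233, adjusted p = 0.0267). sdhB (b0724), the iron-sulfur subunit of succinate dehydrogenase, was 2.79-fold higher, from 8.68 ± 0.19 to 10.17 ± 0.15 (SD, n = 3; limma log2 change 1.48, SE 0.186, adjusted p = 0.00909). Each of these 3 genes was higher with IAA in 3 of 3 same-numbered pairs. They were the only genes past the threshold of limma with Benjamini-Hochberg adjustment, and 0 genes passed it in the other direction. At an unadjusted p below 0.05 there were 470 higher and 511 lower genes, where chance gives 214 in all. The 3 IAA values and the 3 control values did not overlap for 29.6% of genes, against 10% by chance. Neither figure allows for the order of the spots described below. With the position adjustment 354 genes had an unadjusted limma p below 0.05, and the overlap was not counted again.

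With the replicate number as a block, which takes same-numbered cultures as pairs, 21 genes were higher and 13 lower. leuD, aceA and sdhB were among the higher ones. With the quantification batch as a block 5 genes were higher and 1 lower, and within replicates 1 and 2 alone 3 were higher and 0 lower, again leuD, aceA and sdhB. The change of leuD was 1.47, 2.46 and 1.67 on the log2 scale in pairs 1, 2 and 3, that of aceA 1.77, 2.17 and 0.85, and that of sdhB 1.36, 1.82 and 1.26; replicate 3 is a batch of a single pair and gives no test. No gene passed without control replicate 1, with the values as deposited or with a floor at the 10th percentile, where the limma adjusted p of leuD was 0.0945, 0.0519 and 0.142, and leuD alone passed without IAA replicate 1. Over 22 alternatives the adjusted p ranged from 0.000188 to 0.142 for leuD, 0.00115 to 0.175 for sdhB and 0.000455 to 0.21 for aceA.

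**Figure D1:**
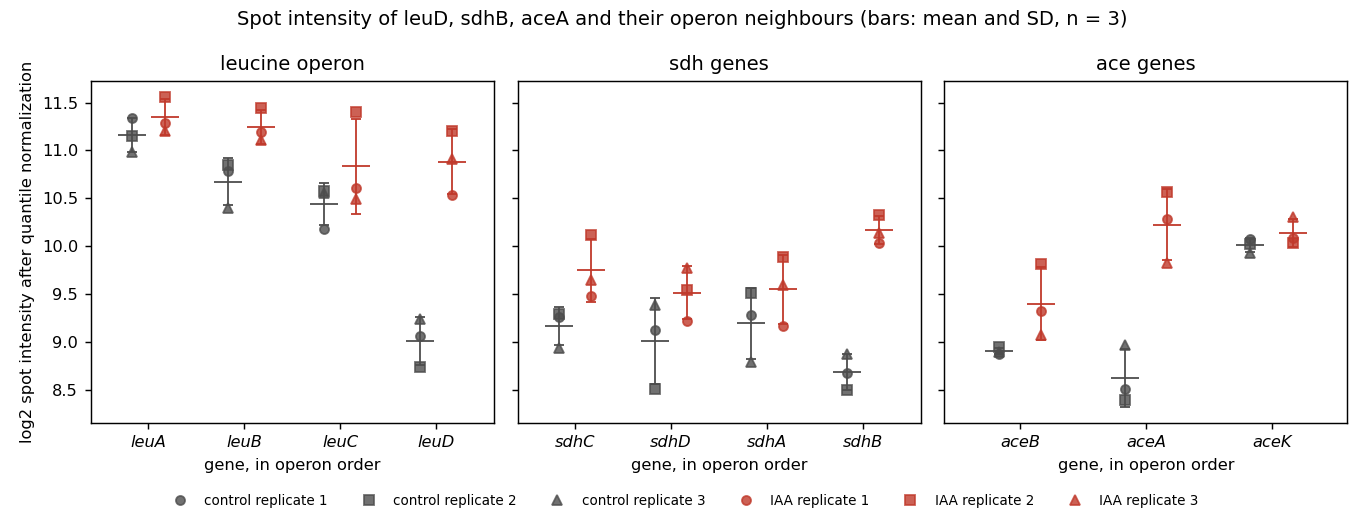
Log2 spot intensity of leuD, sdhB, aceA and the other leu, sdh and ace genes of the same operons in each culture. Controls are in grey and IAA in red, with a symbol per replicate number and mean and SD bars (n = 3). For leuD, sdhB and aceA the 3 IAA values lie above the 3 control values, by 1.87, 1.48 and 1.60 in the mean. The means of the other genes shown differ by 0.13 to 0.59. The suc genes spotted next to sdhB are not shown.

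The genes next in order of p did not pass the threshold in the fit without a block. Among the higher ones were cyoD, a subunit of cytochrome bo oxidase (log2 change 1.06, SE 0.189), sbmA, an inner membrane peptide transporter (1.22, SE 0.227), proA of proline biosynthesis (1.02, SE 0.191), and yfgI (1.07, SE 0.183) and ygaY (1.08, SE 0.203). Their adjusted p in limma lay between 0.0692 and 0.0752, and with the replicate block between 0.0201 and 0.0298. Among the lower ones the largest difference was that of btsT, a pyruvate transporter, at -1.37 (SE 0.225; limma adjusted p = 0.0609, and 0.00942 with the replicate block). ydgI, a putative amino acid antiporter, was at -0.997 (SE 0.195), gfcA at -0.95 (SE 0.179), yihL at -0.97 (SE 0.212), uhpA, a response regulator of sugar phosphate uptake, at -0.91 (SE 0.189) and hisI of histidine biosynthesis at -0.91 (SE 0.189). Their limma adjusted p lay between 0.0752 and 0.101, and with the replicate block between 0.0354 and 0.0492. With the position adjustment described next, cyoD was at 0.74 (SE 0.147) and btsT at -0.99 (SE 0.225), with adjusted p of 0.183 and 0.22 without the block and 0.0468 and 0.0477 with it, and the other genes named here passed in neither fit.

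The log2 change also followed the order of the spots on the array, and this bears on every gene group. It repeated with the spot number at a period of 96, in 12 steps of 8 spots: the median change was 0.40 in step 5 and -0.44 in step 10. The 96 places held 58.5% of the variance of the log2 change across genes, where 1000 shuffles of the spot numbers gave at most 3.36%. In pairs 1, 2 and 3 they held 23.7%, 53.1% and 41.6%, and between cultures of the same group 8.15% to 27.5%. After the position adjustment they held 6.82%, and some order remained: adjacent spots whose genes lie over 20 locus tags apart had log2 changes that correlated at 0.213, against 0.644 before, and spots 96 apart at 0.189, against 0.664. In that fit 1 gene, leuD, was higher by limma (log2 change 1.59, SE 0.174, adjusted p = 0.00815) and 0 were lower, with 200 higher and 154 lower genes at an unadjusted p below 0.05. There aceA was at 1.46 (SE 0.218) and sdhB at 1.06 (SE 0.163), each with an adjusted p of 0.0611. With the position adjustment and the replicate block together, 16 genes were higher and 4 lower, leuD, aceA and sdhB among the higher. Adjusted by place over all blocks instead, 2 genes were higher in limma, leuD (adjusted p = 0.0102) and aceA (adjusted p = 0.0473), and 0 lower, with 163 higher and 142 lower at an unadjusted p below 0.05; sdhB had an adjusted p of 0.149.

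**Figure D2:**
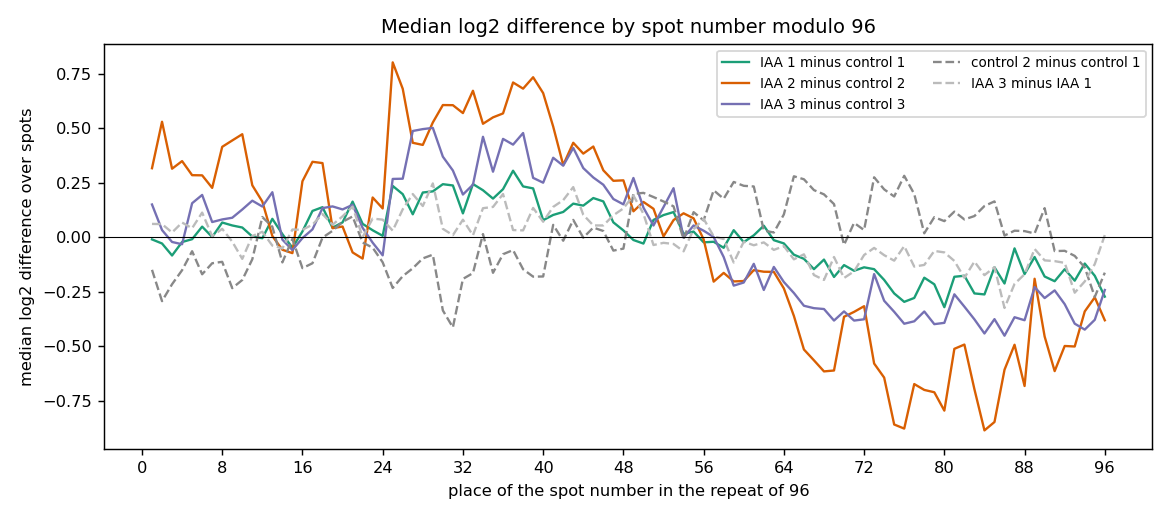
Median log2 difference of the spots at each of the 96 places of the repeat, for the 3 pairs of IAA and control cultures (solid) and for a pair of cultures within each group (dashed). The pairs share a rise near places 25 to 45 and a low stretch after place 60, deepest in pair 2; the places hold 23.7%, 53.1% and 41.6% of the variance in pairs 1, 2 and 3.

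Of the 36 gene lists, camera called 7, 6 of them higher and 1 lower with IAA, and 7 again with the replicate block. With an estimated correlation it called 0, and the lowest adjusted p was 0.403; fry called 4 lists by its main p, proline and 3 others (methionine, translation factors and fatty acids), and 24 by its mixed p. Camera called 7 lists with the quantification batch as a block and 6 within replicates 1 and 2. With the position adjustment it called 6, 3 of them among the 7, and 0 with an estimated correlation as well (lowest adjusted p 0.345). Adjusted by place over all blocks it called 9, with 6 of the 7 among them, all but NADH dehydrogenase and the oxidases. The branched-chain list rose, with a median log2 change of 0.51 and 15 of 15 genes above 0 (camera adjusted p = 2.68e-05). Its genes lie in 3 runs of nearby spots, the largest of 7 genes. The camera adjusted p of the list was 0.403 with an estimated correlation. Over all genes 1 member passed, leuD, and adjusted over the list alone 9 were higher and 6 did not pass. ilvD, dihydroxyacid dehydratase, was at 0.75 (SE 0.194), ilvE, the branched-chain aminotransferase, at 0.64 (SE 0.19) and ilvM, an acetolactate synthase subunit, at 0.80 (SE 0.24). The list's median was 0.30, 0.83 and 0.65 in pairs 1, 2 and 3, and 0.13 after the position adjustment, where it was not called (adjusted p = 0.0684, within 8.64e-07 to 0.403 over 24 alternatives). By place over all blocks it was 0.0998 and called (adjusted p = 0.0388). Position-adjusted, 1 member passed over the list alone, and ilvD, ilvE and ilvM were at 0.32, 0.21 and 0.56.

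The proline list also rose, with a median of 0.56 and 8 of 9 genes above 0 (camera adjusted p = 0.00418, and an adjusted p of 0.403 with an estimated correlation). Adjusted over the list alone 5 genes were higher and 0 passed over all genes. The members with the smallest p were proA and 3 genes that do not make proline: putA, which degrades it, at 0.69 (SE 0.216), and the transporter genes proX at 0.64 (SE 0.213) and putP at 0.56 (SE 0.186). The list's median was 0.31, 0.55 and 0.36 in pairs 1, 2 and 3, and 0.16 after the position adjustment, where it was not called (adjusted p = 0.0684, within 0.000962 to 0.403 over 24 alternatives). By place over all blocks it was 0.174 and called (adjusted p = 0.0157). Position-adjusted, 2 members passed over the list alone, and putA, proX and putP were at 0.65, 0.31 and 0.16. The histidine list was the called list that fell: 0 of 8 genes were above 0, with a median of -0.71 (camera adjusted p = 0.000232, and an adjusted p of 0.403 with an estimated correlation). Adjusted over the list alone 6 genes were lower and 2 did not pass, and 0 passed over all genes. hisC was at -0.70 (SE 0.173), hisH at -0.80 (SE 0.248) and hisD at -0.73 (SE 0.23). The list's median was -0.33, -1.29 and -0.40 in pairs 1, 2 and 3. With the position adjustment it was -0.33 and still called (adjusted p = 0.00746), by place over all blocks -0.255 and called (adjusted p = 0.0281), and it was not called with the dimmest 25% of genes left out (0.0756); over 24 alternatives the adjusted p ranged from 1.41e-05 to 0.403. Position-adjusted, 0 members passed over the list alone, and hisC, hisH and hisD were at -0.33, -0.44 and -0.35.

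The TCA cycle list rose, with a median of 0.44 and 15 of 16 genes above 0 (camera adjusted p = 0.000183, and an adjusted p of 0.403 with an estimated correlation). Its largest run of nearby spots holds 9 of the 16 genes, so their agreement is not that of separately placed genes. sdhB passed over all genes, and adjusted over the list alone 7 genes were higher, 1 was lower and 8 did not pass. sucD, a succinyl-CoA synthetase subunit, was at 0.89 (SE 0.19), sucA, of 2-oxoglutarate dehydrogenase, at 1.01 (SE 0.261), and gltA, citrate synthase, at 0.87 (SE 0.255). The lower one, named here after its value was seen, was acnA, a stress-induced aconitase, at -0.57 (SE 0.207). The list's median was 0.36, 0.85 and 0.37 in pairs 1, 2 and 3. It was 0.19 after the position adjustment and still called (adjusted p = 0.000192, within 8.18e-06 to 0.403 over 24 alternatives), and 0.192 by place over all blocks (adjusted p = 4.36e-05). Position-adjusted, 4 members were higher and 0 lower over the list alone, with sucD, sucA, gltA and acnA at 0.57, 0.61, 0.49 and -0.14. The 5 glyoxylate shunt genes had a median of 0.24 and were not called (adjusted p = 0.0948; position-adjusted median 0.07, adjusted p = 0.237); aceB, malate synthase, was at 0.50 (SE 0.211).

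Both respiratory lists rose in camera. The 9 ATP synthase genes were all above 0, with a median of 0.39 (adjusted p = 0.0155, and an adjusted p of 0.403 with an estimated correlation). They form 1 run of nearby spots, so their agreement is not that of separately placed genes. Of these genes 0 passed over all genes or adjusted over the list alone. atpE was at 0.46 (SE 0.187) and atpH at 0.50 (SE 0.215). Of the 25 genes of NADH dehydrogenase and the cytochrome oxidases 21 were above 0, with a median of 0.24 (adjusted p = 0.0155, and an adjusted p of 0.507 with an estimated correlation). Adjusted over the list alone 2 were higher, and 0 passed over all genes; cyoA was at 0.79 (SE 0.209) and nuoK at 0.64 (SE 0.209). In pairs 1, 2 and 3 the ATP synthase median was 0.28, 0.50 and 0.35, and that of NADH dehydrogenase and the oxidases 0.11, 0.38 and 0.24. The position adjustment left the ATP synthase median at 0.09 (adjusted p = 0.111) and turned that of NADH dehydrogenase and the oxidases to -0.10 (adjusted p = 0.576). Adjusted by place over all blocks, ATP synthase was at 0.235 and called (adjusted p = 0.00483), and NADH dehydrogenase and the oxidases were at -0.13 (adjusted p = 0.522). ATP synthase was also not called with the values as deposited (adjusted p = 0.134), with median centring (0.128), with the dimmest 25% of genes left out (0.155), with a floor at the 10th percentile (0.0521), without control replicate 1 (0.0693) or without IAA replicate 3 (0.0679). NADH dehydrogenase and the oxidases were also not called within replicates 1 and 2 alone (camera adjusted p = 0.0547). Position-adjusted, 0 ATP synthase genes passed over their list alone, and of NADH dehydrogenase and the oxidases 1 was higher and 1 lower; atpE, atpH, cyoA and nuoK were at 0.29, 0.29, 0.46 and 0.19. Over 24 alternatives the adjusted p ranged from 0.00483 to 0.403 for ATP synthase and from 0.00365 to 0.576 for NADH dehydrogenase and the oxidases.

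Heat shock proteins and chaperones rose as a list, with a median of 0.31 and 15 of 21 genes above 0 (camera adjusted p = 0.0257, and an adjusted p of 0.403 with an estimated correlation). Adjusted over the list alone 4 were higher and 17 did not pass, and 0 passed over all genes. hslO, the redox-regulated chaperone Hsp33, was at 0.92 (SE 0.245), dnaK, the main Hsp70, at 0.70 (SE 0.186), htpG, the Hsp90 homologue, at 0.69 (SE 0.209) and hslR at 0.62 (SE 0.188). The median was 0.29, 0.37 and 0.07 in pairs 1, 2 and 3. Following the position adjustment it was 0.26 with 18 of 21 genes above 0, and still called (adjusted p = 0.000192), and by place over all blocks 0.314 (adjusted p = 3.44e-05). Position-adjusted, 0 members passed over the list alone, and hslO, dnaK, htpG and hslR were at 0.64, 0.63, 0.42 and 0.35. The list was not called without control replicate 1, control replicate 2 or IAA replicate 1 (adjusted p of 0.0577, 0.0597 and 0.19, within a range of 3.44e-05 to 0.403 over its 24 alternatives). Its median fell to 0.13 without control replicate 2, and to 0.145 without IAA replicate 2, where it was called (adjusted p = 0.0172).

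**Figure D3:**
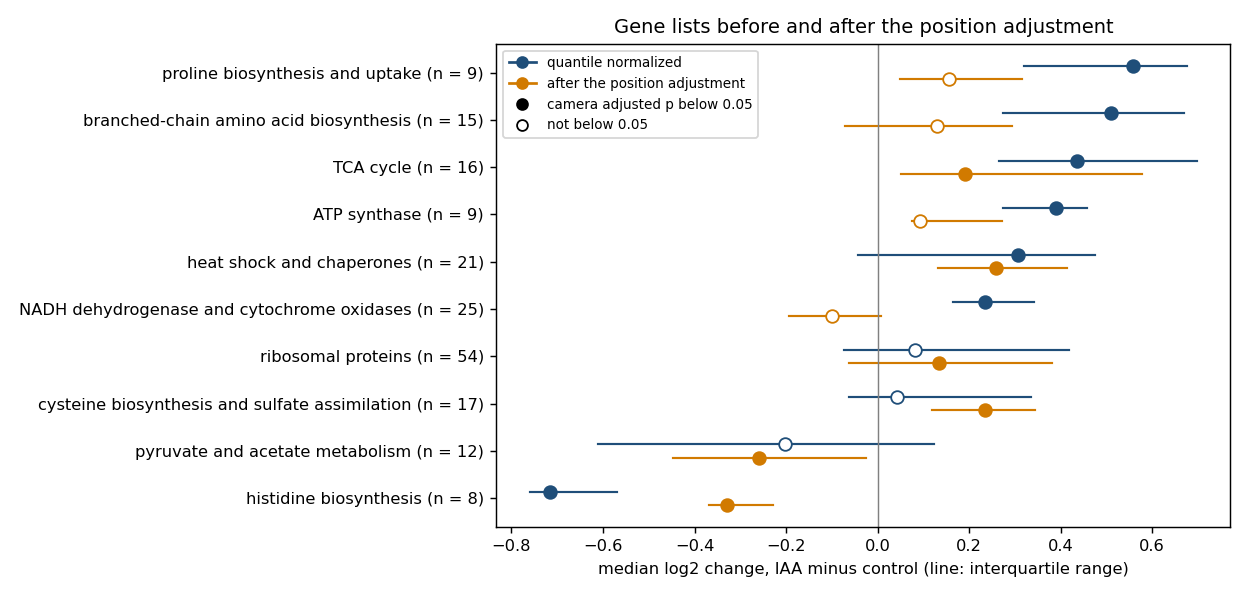
Median log2 change of the genes in each list that camera called before (blue) or after (orange) the position adjustment, IAA minus control, with the interquartile range over its genes as a line; filled points have an adjusted p below 0.05 at the preset correlation. TCA cycle, heat shock and histidine are filled in both, while NADH dehydrogenase and the oxidases go from 0.24 to -0.10.

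Camera called none of the other 29 lists, with adjusted p between 0.0932 and 0.977. This does not mean that their genes were unchanged, as fry's mixed p called 24 of the 36 lists without position adjustment. For genes close to the chemistry of IAA, the list of tryptophan and aromatic amino acid biosynthesis had a median of -0.07 over 21 genes (adjusted p = 0.435; position-adjusted -0.14, adjusted p = 0.195), with trpB, tryptophan synthase, at -0.49 (SE 0.182), and at -0.38 when position-adjusted. The 6 genes of tryptophan uptake and indole formation had a median of 0.20 (adjusted p = 0.524; position-adjusted 0.07, adjusted p = 0.661), with 3 above 0 and 3 below. Above 0 were tnaA, tryptophanase, at 0.49 (SE 0.199), its leader gene tnaC at 0.60 (SE 0.203) and the tryptophan transporter mtr at 0.74 (SE 0.284), which were at 0.13, 0.22 and 0.43 when position-adjusted. tnaB, of tryptophan uptake, was below 0 at -0.42 (SE 0.219; position-adjusted -0.27). The 8 arabinose genes, which serve the carbon source, had a median of 0.06 (adjusted p = 0.977; position-adjusted -0.05, adjusted p = 0.899), with araF, the binding protein for uptake, at -0.57 (SE 0.187) and araA, arabinose isomerase, at 0.38 (SE 0.202), and these were at -0.17 and 0.29 when position-adjusted.

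Camera did not call the lists of other stress responses either. Their medians were 0.06 for the general stress regulon (adjusted p = 0.687), -0.15 for acid resistance (adjusted p = 0.303), -0.06 for oxidative stress (adjusted p = 0.524), 0.12 for the SOS response (adjusted p = 0.918), 0.04 for envelope stress (adjusted p = 0.395) and 0.03 for multidrug efflux (adjusted p = 0.977). In the same order the position-adjusted medians were 0.00277, -0.06, 0.00826, -0.0146, 0.0916 and -0.0684, with adjusted p from 0.0781 for envelope stress upwards. Adjusted over the list alone, 1 acid resistance gene was higher and 4 were lower, and 0 passed when position-adjusted. By fry's mixed adjusted p, without position adjustment, acid resistance (0.0133), multidrug efflux (0.0131) and the general stress regulon (0.0404) were called. Oxidative stress (0.244), SOS (0.0827) and envelope stress (0.0836) were not. Flagella and chemotaxis had a median of -0.18 (adjusted p = 0.0932), fatty acid metabolism 0.26 (adjusted p = 0.0932), and translation factors with RNA polymerase 0.32 (adjusted p = 0.0932); position-adjusted they were at -0.0023, 0.00506 and 0.07, with adjusted p of 0.833, 0.847 and 0.457.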

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

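A spot outside the genes gave a value far above the controls. A grid position row (field 3 of the first grid) read 40821 in column b of IAA replicate 1, more than 3 times the highest control column, which was 2789. The duplicate in column a of the same culture read 2892, and the highest of the other IAA columns 4237, so the value stands in 1 column only. It enters no comparison.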

How the results depend on the processing

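The counts of genes past the threshold moved with many of the alternatives. The position adjustment, the quantification batch, the spot values at 0 taken as missing and the duplicates as deposited were chosen after seeing the data. Against 3 higher and 0 lower genes, counts of higher genes were 0 with the values as deposited and 0 with a floor at the 10th percentile (2 with median centring), 5 with column a, 1 with column b, 31 with the 12 columns and culture as a random block, 21 with the replicate block, 5 with the quantification batch as a block, 1 with the position adjustment and 16 with that and the replicate block. They were 18 at an adjusted p below 0.10 and 10 by the first reading of the selection rule in the series text (2 by the second). Lower genes numbered 24 with the random block, 13 with the replicate block, 4 with position adjustment and replicate block, 1 with the batch block, 1 with a variance trend, 7 at an adjusted p below 0.10 and 5 by the first reading. Leaving out a culture gave 0 to 4 higher and 0 to 0 lower genes; it was 0 without control replicate 1 and 1 without IAA replicate 1. Fewer cultures leave fewer degrees of freedom; the cause of the other moves was not tested. Lists called were 7, 0 with an estimated correlation and 4 with fry, and 6 to 10 in every other alternative run. The 7 lists kept their direction in every alternative except NADH dehydrogenase and the oxidases, which went to -0.10 with the position adjustment, -0.13 with it over all blocks and -0.10 with it and the replicate block. Cysteine genes went from 0.0429 to -0.0208 with the values as deposited. Pairing by replicate block changed no list call. The 55 genes followed by symbol, those named in the text, kept their direction in every alternative run, but of the 153 picked by the naming rule 12 reversed with the position adjustment, to at most 0.111 in size. The median r of duplicate spots was 0.965 after quantile normalization and 0.966 as deposited. A filter on repeated lowest values was not run, since no column has them. Signal over background cannot be given, as the values carry no background.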

Other observations

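These were chosen after the results they bear on were seen: the position adjustment, the place-based tests of log2 change and of the 7 called lists. The same holds for the comparison of place shifts within operons, and for the genes and lists of the next paragraph and the one after it.

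Camera called 3 further lists with the position adjustment. Cysteine biosynthesis and sulfate assimilation had a median log2 change of 0.23 over 17 genes (adjusted p = 0.0028), ribosomal proteins 0.13 over 54 genes (adjusted p = 0.00425), and pyruvate and acetate metabolism -0.26 over 12 genes (adjusted p = 0.00425). Before the adjustment their medians were 0.0429, 0.081 and -0.202 (camera adjusted p of 0.435, 0.0932 and 0.171). After it none of these lists was called with an estimated correlation, where their camera adjusted p were 0.385, 0.385 and 0.345. Members of the ribosomal list with the smallest p before adjustment were rpmA, rplM, rplS and rpmI, at 1.08, 0.78, 0.88 and -0.83. After it they were at 0.67 (SE 0.177), 0.45 (SE 0.161), 0.76 (SE 0.167) and -0.52 (SE 0.173). In the pyruvate and acetate list aceE, of pyruvate dehydrogenase, was at -0.67 (SE 0.174), adhE, of ethanol formation, at -0.39 (SE 0.166) and pflB, pyruvate formate-lyase, at -0.76 (SE 0.161) after adjustment. Before it aceE, adhE and pflB were at -0.61, -0.81 and -0.62.

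In limma with position adjustment and replicate block 4 genes were lower: btsT, the pyruvate transporter, at -0.99 (SE 0.201, adjusted p = 0.0477), its genome neighbour yjiX at -0.82 (SE 0.151, adjusted p = 0.0384), pflB at -0.76 (SE 0.149, adjusted p = 0.0468) and nrfE, of nitrite reduction, at -1.04 (SE 0.17, adjusted p = 0.0242). btsT and yjiX have consecutive locus tags but lie far apart in spot number, 1243 and 4272. Among the 16 higher genes were pspA, the phage shock protein, at 1.26 (SE 0.216, adjusted p = 0.0246), mglB, the galactose binding protein, at 1.06 (SE 0.191, adjusted p = 0.0364), fumC, a fumarase, at 0.86 (SE 0.16, adjusted p = 0.0384), and an unnamed spot, number 2890, at 1.26 (SE 0.158, adjusted p = 0.00318). Of the 21 higher and 13 lower genes called with the replicate block alone, 6 and 1 were called with the position adjustment as well.

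The log2 change repeated with the spot number at a period of 96, and the places of the repeat held 58.5% of its variance. Genes of an operon spotted side by side cannot account for this: adjacent spots whose genes lie over 20 locus tags apart had log2 changes that correlated across genes at 0.644 (1016 pairs of spots), while genome neighbours over 20 spot numbers apart correlated at 0.0184 (2530 pairs of genes). The quantile normalization done here is not its source either, since the places held 56.9% of the variance in the values as deposited, above the 3.55% of the highest of 1000 shuffles. A candidate explanation is a difference in spot size, exposure or hybridisation across the membranes or the plates they were printed from, but the layout is not known here. The places held 23.7% to 53.1% in the 3 pairs and 8.15% to 27.5% between cultures of a group; these ranges overlap, since pair 1 lies below the highest value within a group. A membrane lot, hybridisation or filter set shared by the IAA cultures stays open, and no biological explanation was tested.

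The lists that moved as a whole were set against random lists matched on place or on brightness. For brightness, 7 of 7 called lists had medians before adjustment outside the central 95% of 10000 lists matched on mean intensity. Those random lists were drawn gene by gene and lack the runs of nearby spots, whose log2 changes go together. A shared place could therefore put a list outside, and this comparison does not decide on brightness. Position-adjusted, 4 of the 7 lay outside. Proline, ATP synthase and NADH dehydrogenase with the oxidases lay inside, at percentiles of 95.27, 73.89 and 4.09. The place of the spot in a repeat of 96 was tested with 10000 random lists matched on place, and with 10000 matched on spacing too, where runs of nearby spots moved as a whole by blocks of 96. As the whole cause it was argued against for the list of heat shock, and less firmly for that of histidine. Their medians lay at percentiles of 99.95 and 0 of the former and 99.96 and 0 of the latter. With the position adjustment the latter were 100 and 0. The histidine genes form 1 run with 43 possible moves, so their spacing-matched lists hold at most 43 distinct ones. A percentile of 0 there says only that none of these had a lower median. The lists matched on place alone were drawn gene by gene, without that run. Camera called both lists after both forms of position adjustment at the preset correlation, but not with an estimated correlation after the position adjustment (adjusted p = 0.345 for each).

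The evidence on place was divided for 4 lists. TCA cycle lay at a percentile of 98.58 of the lists matched on place, but at the edge of those matched on spacing too (97.41, and 97.84 position-adjusted), and camera called it after both forms of adjustment. The branched-chain list lay at 97.55 and 93.69, proline at 99.13 and 99.98, and ATP synthase at 94.33 and 98.09, and position-adjusted at 79.79, 94.6 and 91.42. These 3 lost their call with the position adjustment (adjusted p of 0.0684, 0.0684 and 0.111) and kept it by place over all blocks (0.0388, 0.0157 and 0.00483). For the 4 lists an effect of place cannot be told apart from another cause. NADH dehydrogenase with the oxidases lay at 17.8 and 15.94 and was called after neither form, so place could account for its rise. Position-adjusted it lay on the low side, at 1.31, with 7 of 25 genes above 0. An effect of IAA on the other 6 lists stays open as a hypothesis, next to membrane effects that place does not capture.

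leuD, sdhB and aceA rose more than the other leu, sdh and ace genes spotted beside them. The excess was 1.48 ± 0.33, 0.999 ± 0.34 and 1.29 ± 0.62 on the log2 scale (SD, n = 3 pairs). For sdhB the genes compared were sdhC, sdhD and sdhA. The suc genes spotted next to it were left out, and of these sucA and sucD, chosen for a small p, rose by 1.01 and 0.89. leuD, sdhB and aceA were singled out for their size, so part of the excess may come from that choice. A single faulty spot was argued against, since the smallest excess in column a or column b alone was 0.868. The neighbours compared lie within 3 spot numbers. Places so close can still differ in the repeat of 96: the median change was 0.064 at place 24 and 0.459 at place 25. Adjusted by place over all blocks, the shift subtracted from a gene exceeded that of its neighbours by at most 0.0716. The excess less its SD was 1.15, 0.66 and 0.67 for leuD, sdhB and aceA, so that shift is too even to account for the excess. The other form of position adjustment pools adjacent places, so little difference could show there. A shift at a single spot is captured by neither form. Cross-hybridisation, a spotting fault shared by both duplicates, and processing of the operon transcripts were not tested and stay open.

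The 6 cultures can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 3 genes, and 1 of the 10 splits gave as many; the highest of the others was 0. It gave 7 lists, and 1 of the 10 gave as many, with 6 the highest of the others. With the position adjustment it gave 1 gene, and 1 of the 10 splits gave as many, against 0 in the others. Of the other splits, the 3 that part every same-numbered pair gave at most 4 lists and the 6 that keep a pair together at most 6.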
